A study of Mus musculus with 42 samples.

How the data were processed

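Gene expression was measured by bulk RNA sequencing in 42 cultures of bone marrow-derived macrophages from male wild-type C57BL/6 mice. Per the labels' protocols, cells were grown from whole bone marrow with macrophage colony-stimulating factor, and no sorting step is described. Total RNA was isolated with a column kit that included DNase, and libraries were made with the NEBNext Ultra RNA kit. Reads were processed with STAR and the mm10 genome build per the submitters' processing notes, which give no version and do not name the counting program, the annotation release, the filters or the strand setting. Reads of overlapping genes on opposite strands may therefore have been shared. The authors deposited a table of raw gene counts, whole numbers with 1 column per sample, and this table was the source of all results. The authors also deposited a table of FPKM values. In it the library size implied by count, gene length and FPKM was 1.13 to 1.28 times the total count in libraries without LPS and 0.65 to 0.763 times in libraries with LPS, and FPKM values served for this check alone. Gene names, identifiers and positions were taken from the count table, which pairs them, and are in mm10.

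Every column was matched to a sample through the column label given in the sample's description, and groups followed the stated age and treatment. Total counts per library ran from 39850835 to 67347866. The count filter (filterByExpr with a minimum count of 10) left 17648 of 54532 genes, or 32.4%, which held at least 99.98% of the counts of each library. With 3 counts over a control group as the floor, the lowest level against which a fold was computed was 0.00888 CPM in young and 0.016 CPM in aged controls for Tnf and any other gene.

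Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, and 1 negative binomial model was fitted to all 42 libraries with 12 groups, a trended dispersion and a robust quasi-likelihood step (glmQLFit with legacy off). The labels do not explain why young control and young LPS hold replicates 4 to 6, so the model had a term for these 6 libraries. All 6 young controls entered the treatment comparisons with the difference between the sets taken out by this term, and for comparisons between ages the young mean was placed halfway between the sets. A total of 19 comparisons were tested with the quasi-likelihood F test, and p was adjusted by Benjamini-Hochberg over all tested genes within each comparison, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. Log2 CPM values used a prior count of 2. The differences of effects between ages, and of the LPS effect with and without earlier β-glucan, were contrasts of the same model.

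A total of 38 gene lists and 30 key genes were written before the data were examined, as were the comparisons, the tests and the alternatives, except where stated. Lists were tested with cameraPR of limma 3.58.1 on the signed statistics of each comparison, with an inter-gene correlation of 0.01, and again with camera on voom values with an estimated correlation. Both were adjusted over the lists of a comparison. List members were also adjusted over the list alone. Of 722 list tests 165 passed with the preset correlation, and of these 26 passed also with the estimated one. In 32 of the 722 the direction was opposite under the estimated correlation, and no list passed with that correlation alone. Genes named in the report were chosen from those taken by a fixed rule. It took the 5 largest rises and the 5 largest falls among called genes with a mean log2 CPM of at least 3, a proper symbol and, between 2 groups, libraries that did not overlap. It also took the key genes, and up to 4 members of each list with the smallest adjusted p in the direction of the list median. For lists that mark other cell types it took the most abundant members. Part of the genes so taken were named, and 1 that had been named is not reported here.

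The 200 genes most induced and the 200 most repressed by LPS were chosen from young replicates 4 to 6 and tested under priming in young replicates 1 to 3 and in aged cells, so that no library served both steps. The 95% intervals of list medians came from 2000 bootstrap draws over members, and those between libraries from Welch t intervals of list means per library. Each fold against a group at 0 counts was computed from a floor of 3 counts over the group.

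The model was tested on simulated counts with the real means, library sizes and 200 changed genes with a mean log2 CPM of at least 3. In the young 3-day comparison (17194 genes) it recovered 79.1%, 97% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 5.64% of calls false. In the aged 3-day comparison (17189 genes) these were 74.6%, 95.5%, 100% and 6.25%, and in the age difference of the 3-day effect (17206 genes) 46.3%, 83.6%, 98.5% and 5%. With the tool's default single dispersion 17.2%, 27.5% and 18.7% of calls were false. The trended dispersion was therefore adopted after real results had been seen, and the single dispersion was run as an added alternative. The difference between the young sets was not tested this way.

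The alternatives were RLE scaling, DESeq2 1.42.0 with its Wald test, no count filter, no set term, the replicate number as a block, young replicates 1 to 3 alone, young replicates 4 to 6 alone, the compared groups fitted alone, and each library of the compared groups left out in turn. Total-count scaling, the single dispersion, the scaling and filter alternatives of the LPS-defined lists and of the overlap, and the concordance over expressed genes were added after seeing the data. Calls were also counted for other splits of the same libraries, with up to 100 splits per comparison and 50 for the differences of effects, refitting the libraries of the compared groups alone with a binned dispersion. No library was left out of the main model.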

Results

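Transcripts of bone marrow-derived macrophages from male wild-type C57BL/6 mice were counted by bulk RNA sequencing in 42 libraries of 12 groups. The mice were young (10 to 12 weeks) or aged (18 to 20 months), and the same 6 treatments were given at both ages. β-glucan, a fungal cell-wall polysaccharide bound by the receptor Dectin-1, was given at 5 µg/mL for 4 h, for 24 h, or for 24 h with collection on day 3 afterwards. Lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4, was given at 100 ng/mL for 4 h, to naive cells or to cells exposed to β-glucan beforehand, called primed cells here. Control cells had received 0.1% normal saline for 24 h and were collected on day 3, the only control time given, so the 4 h and 24 h β-glucan comparisons also differ from it in time, and the culture time of naive LPS cells is not given. Each group held 3 libraries, except for the young control and young LPS groups with 6. Total counts per library ran from 39850835 to 54477261 in the young groups and from 40102513 to 67347866 in the aged groups, and 17648 genes were tested. A gene was called when its adjusted p (edgeR quasi-likelihood test, Benjamini-Hochberg over all tested genes) lay below 0.05, and the adjusted p of a gene list comes from camera, with Benjamini-Hochberg over the lists. Changes are log2 fold changes ± SE from the edgeR fit, n = 3 libraries per group (6 in the young control and young LPS groups), and levels are counts scaled to the library size (CPM) ± SD. Young replicates 4 to 6 exist for control and LPS alone. They differed from replicates 1 to 3 in 3074 genes (1582 higher and 1492 lower, edgeR quasi-likelihood test). The model had 1 term for this set, the same in control and LPS cells, and levels pool both sets. Largest changes are those among called genes with a mean log2 CPM of at least 3. Positions are in mm10.

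**Figure D1:**
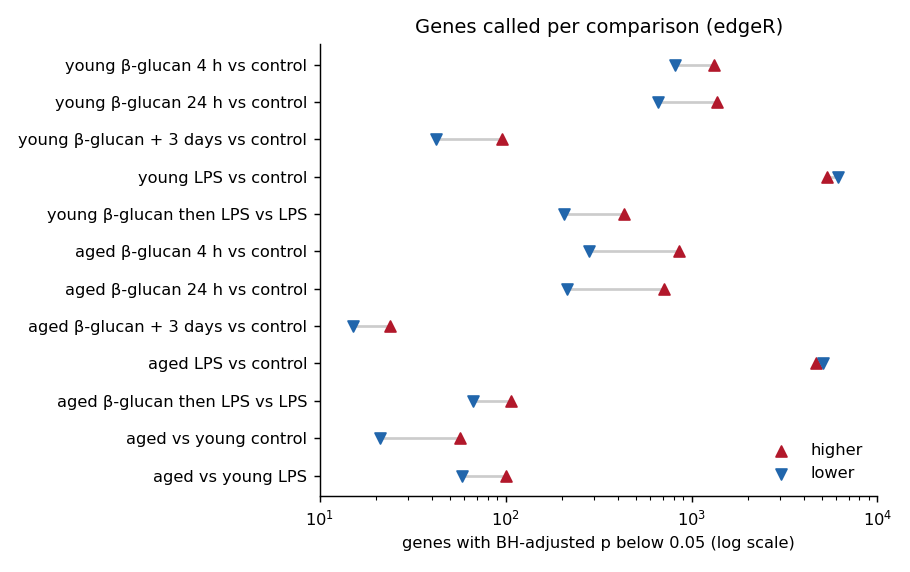
Number of genes past an adjusted p of 0.05 in each comparison between 2 groups, higher (red) and lower (blue), on a log axis. LPS alone called 11478 genes in young and 9798 in aged cells, and the 3-day β-glucan comparison 138 and 39.

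Young macrophages were first compared after 4 h of β-glucan. Inflammatory mediators, feedback regulators of NF-κB, antioxidant genes of the NRF2 pathway and stress-response genes rose within this time. Some receptor genes fell, among them the mannose receptor Mrc1 and the efferocytosis receptor Mertk. The chemokine gene Cxcl2 (4.58 ± 0.38, edgeR adjusted p = 2.34e-10) rose most among the named genes (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938). Next came Acod1 (4.00 ± 0.29, edgeR adjusted p = 8.92e-12, ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), the itaconate-producing enzyme, and the cystine transporter Slc7a11 (3.95 ± 0.32, adjusted p = 1.47e-10, ENSMUSG00000027737, chromosome 3, 49892526 to 50443614). The prostaglandin synthase Ptgs2 (3.70 ± 0.33) and Tnf (3.60 ± 0.2) followed, Tnf going from 33.3 ± 16 to 330 ± 45 CPM. The largest falls were in Abcg3 (-1.61 ± 0.23), Mtus1 (-1.58 ± 0.24), the ERK phosphatase Dusp6 (-1.57 ± 0.2, edgeR adjusted p = 5.34e-07), Slc46a3 (-1.56 ± 0.2) and Rnf150 (-1.35 ± 0.15). Of 28 NF-κB feedback regulators 22 rose and the other 6 did not pass (median 1.24, 25 up adjusted over the list alone), such as the inhibitors Nfkbia (2.18 ± 0.15) and Tnfaip3 (1.98 ± 0.16). Of 34 cytokines and chemokines 14 rose, 1 fell and 19 did not pass (median 1.70), with Ccl3 (2.05 ± 0.12), Ccl4 (2.16 ± 0.12) and the receptor antagonist Il1rn (2.72 ± 0.26). In the list of pentose phosphate and NRF2 genes 16 of 25 rose and the other 9 did not pass (median 0.44), such as Txnrd1 (1.56 ± 0.14) and Srxn1 (1.87 ± 0.19). The stress list had 13 of 27 up, with Ppp1r15a (1.66 ± 0.17) and Trib3 (1.94 ± 0.25), and the hypoxia list 9 of 21 up, with Hif1a (0.60 ± 0.1) and Slc2a1 (1.41 ± 0.19). These 5 lists moved as sets (adjusted p = 1.17e-34, 2.25e-13, 9.63e-17, 8.8e-11 and 5.95e-06, camera), and each passed too with an estimated correlation (0.00046, 0.0126, 0.0211, 0.00046 and 0.000762).

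Among receptors and adaptors for microbial patterns in young cells at 4 h, 11 of 34 rose and 4 fell (median 0.17, camera adjusted p = 0.00366, and adjusted p = 0.219 with an estimated correlation). Tlr2 (1.56 ± 0.12), the C-type lectin Clec4e (2.96 ± 0.28) and the inflammasome sensor Nlrp3 (1.32 ± 0.15) rose, and Tlr4 (-0.50 ± 0.13) fell. Phagocytic receptors fell more often than they rose (6 against 2 of 27, not passing as a set), with Mertk (-0.71 ± 0.11), Fcgr3 (-0.45 ± 0.086), Mrc1 (-0.66 ± 0.14) and Fcgr1 (-0.76 ± 0.15) lower. Of 46 interferon-stimulated genes 10 rose and the other 36 did not pass (camera adjusted p = 0.0559), such as Rsad2 (1.79 ± 0.3) and Cxcl10 (2.55 ± 0.43). The antimicrobial list had 8 of 25 up (camera adjusted p = 1.05e-05, and adjusted p = 0.15 with an estimated correlation), with Casp4 (1.39 ± 0.098) and Cybb (0.65 ± 0.13). Glycolysis genes rose in 9 and fell in 1 of 24 (camera adjusted p = 0.000198, and adjusted p = 0.219 with an estimated correlation), with Pfkp (0.92 ± 0.13) and Pfkfb3 (0.57 ± 0.099). In cholesterol synthesis 6 of 25 rose (camera adjusted p = 0.0109, and adjusted p = 0.526 with an estimated correlation), with Insig1 (0.55 ± 0.08). At an adjusted p below 0.05, 1314 genes rose and 814 fell, and 4059 had an unadjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 against 6). Scaling by total counts, which moved the median of all genes by -0.11, gave 867 up and 1588 down. Without single libraries the count ran from 1434 to 2404.

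The next comparison asked the same of aged macrophages. The 3 largest rises were in the same genes as in young cells, and the cytokine, NF-κB, antioxidant and stress programmes rose again. Cxcl2 (4.60 ± 0.45, edgeR adjusted p = 1.17e-08), Acod1 (4.42 ± 0.34, adjusted p = 1.07e-10) and Slc7a11 (4.07 ± 0.38, adjusted p = 4.09e-09) rose most, followed by Ptgs2 (3.85 ± 0.41) and the chemerin receptor Ccrl2 (3.43 ± 0.29). The largest falls were in Dusp6 (-1.55 ± 0.21, edgeR adjusted p = 2.1e-06), Enc1 (-1.25 ± 0.2), Mtus1 (-1.21 ± 0.24), Abcg3 (-1.21 ± 0.24) and Nfatc2 (-1.13 ± 0.16). Tnf went from 23.9 ± 2.4 to 212 ± 39 CPM (3.15 ± 0.22). Of 28 NF-κB feedback regulators 21 rose and the other 7 did not pass (median 1.15, 22 adjusted over the list alone), with Nfkbia (2.33 ± 0.17) and Nfkbie (2.33 ± 0.2). Of 34 cytokines 14 rose and the other 20 did not pass (median 1.07), with Ccl3 (1.26 ± 0.13) and Ccl4 (1.14 ± 0.13). NRF2 genes rose in 13 of 25 (median 0.55), with Sqstm1 (1.61 ± 0.16) and Txnrd1 (1.45 ± 0.16), and stress genes in 11 of 27 (median 0.30), with Atf3 (0.95 ± 0.11) and Mthfd2 (0.94 ± 0.15). The hypoxia list had 6 of 21 up (median 0.24), with Ero1l (0.89 ± 0.11) and Slc2a1 (1.29 ± 0.21), and the mTOR and HIF-1 list 6 up and 1 down of 26 (median 0.17), with the amino acid transporter Slc7a5 (1.43 ± 0.27). All 6 lists passed (adjusted p = 3.71e-37, 9.34e-11, 1.4e-19, 8.33e-08, 0.00325 and 0.000439, camera) and did so with an estimated correlation (0.00072, 0.0246, 0.016, 0.00179, 0.0246 and 0.016). Among pattern receptors 8 of 34 rose and 3 fell (camera adjusted p = 0.00897, and adjusted p = 0.318 with an estimated correlation), with Tlr2 (1.89 ± 0.13), Clec4e (2.92 ± 0.32) and Nod2 (1.16 ± 0.19) higher. Mertk (-0.62 ± 0.11) and Fcgr3 (-0.43 ± 0.091) fell, as did 4 of 27 phagocytic receptors in all.

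In aged cells 860 genes rose and 281 fell at 4 h, and 2829 had an unadjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 against 3). Total-count scaling gave 597 up and 519 down, and 755 genes were called without aged β-glucan 4 h replicate 3. The chemokine gene Ccl4 (-1.02 ± 0.18, edgeR adjusted p = 0.0263) alone differed in its response between the ages (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683). It rose by 2.16 ± 0.12 in young cells, from 21.5 ± 1.9 to 87.1 ± 4.2 CPM, and by 1.14 ± 0.13 in aged cells, from a higher control level, 32.2 ± 5.1, to 71.1 ± 5.7 CPM. The call ended without the count filter (edgeR adjusted p = 0.136), without the set term (0.418), with young replicates 1 to 3 alone (0.08), with the groups fitted alone (0.108), without young control replicate 2 (0.0542), young β-glucan 4 h replicates 1 (0.078), 2 (0.0578) and 3 (0.17), aged control replicates 1 (0.0627) and 3 (0.4) and aged β-glucan 4 h replicates 1 (0.247) and 2 (0.132). No other gene differed (edgeR quasi-likelihood test, 586 with an unadjusted p below 0.05, and 6 called by DESeq2). The neighbouring chemokine gene Ccl3 (-0.79 ± 0.18, edgeR adjusted p = 0.344) and Tnf (-0.46 ± 0.28, adjusted p = 1) did not pass. The cytokine list had a median difference of -0.26 (camera adjusted p = 0.0151), but adjusted p = 0.896 with an estimated correlation.

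Young macrophages were examined next after 24 h of β-glucan. An interferon signature, antigen presentation by MHC class I, some lysosomal enzymes and markers of the osteoclast lineage rose, and the monocyte genes F13a1 and Cx3cr1 fell. Tnf stood at 41.5 ± 6.6 CPM against 33.3 ± 16 in controls of both sets. Rsad2 (viperin) was at 46.5 ± 22 against 9.64 ± 2.7 CPM. The largest rises were in the MHC class Ib gene H2-M2 (3.44 ± 0.33, edgeR adjusted p = 1.78e-08, ENSMUSG00000016283, chromosome 17, 37480851 to 37483552) and the endothelial protein C receptor Procr (3.14 ± 0.2, adjusted p = 2.47e-13, ENSMUSG00000027611, chromosome 2, 155751117 to 155755471). The kinase Src (3.09 ± 0.45), Slamf8 (2.99 ± 0.4) and the receptor Met (2.66 ± 0.31) came next. The coagulation factor F13a1 (-2.38 ± 0.36, edgeR adjusted p = 2.15e-05, ENSMUSG00000039109, chromosome 13, 36867178 to 37050244) and Fcrls (-1.75 ± 0.28) fell. So did Cx3cr1 (-2.21 ± 0.51), Pmepa1 (-2.15 ± 0.54) and Ctla2a (-1.81 ± 0.41). The call of Cx3cr1 ended with the groups fitted alone (edgeR adjusted p = 0.124) and without young β-glucan 24 h replicate 1 (0.0556), that of Pmepa1 with the groups fitted alone (adjusted p = 0.205) and without young β-glucan 24 h replicates 1 (0.0887) and 3 (0.0743), and that of Ctla2a with the groups fitted alone (adjusted p = 0.0526) and without young β-glucan 24 h replicate 1 (0.0544). Of 46 interferon-stimulated genes 41 rose and the other 5 did not pass (median 1.27, 45 adjusted over the list alone), with Irf7 (2.21 ± 0.32), Rsad2 (2.41 ± 0.3) and Oas3 (1.80 ± 0.27). The list passed (camera adjusted p = 6.8e-30), and had adjusted p = 0.109 with an estimated correlation. Its level in the young 24 h libraries was 4.81, 3.64 and 4.37 (mean log2 CPM of the interferon-stimulated genes), against 3.19 ± 0.3 in controls.

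Osteoclast genes rose in 7 of 10 in young cells at 24 h (median 1.62, camera adjusted p = 1.71e-08), with the integrin Itgb3 (2.39 ± 0.24) and the proton pump subunit Atp6v0d2 (1.32 ± 0.23). This list passed with an estimated correlation too (0.00263), as did the lysosome list (20 up and 2 down of 36, median 0.26, camera adjusted p = 4.01e-13, estimated 0.0412), with Ctsz (0.78 ± 0.088), Psap (0.78 ± 0.11) and Gpnmb (0.67 ± 0.098). MHC class I genes rose in 16 and fell in 2 of 21 (median 0.56, camera adjusted p = 2.11e-13, and adjusted p = 0.106 with an estimated correlation), with Tapbp (0.98 ± 0.14) and H2-D1 (1.01 ± 0.14). Antimicrobial genes rose in 16 of 25 (camera adjusted p = 1.7e-11, and adjusted p = 0.0663 with an estimated correlation), with Cyba (0.87 ± 0.1) and Cybb (0.88 ± 0.13). NRF2 genes rose in 16 of 25 (camera adjusted p = 8.97e-12, and adjusted p = 0.109 with an estimated correlation), with Prdx6 (0.92 ± 0.1) and Slc7a11 (2.61 ± 0.32). NF-κB regulators still had 14 of 28 up and cytokines 14 of 34 (camera adjusted p = 9.44e-10 and 4.14e-07, both adjusted p = 0.109 with an estimated correlation), with Traf1 (1.92 ± 0.28), Il1rn (2.47 ± 0.26) and Ccl4 (1.40 ± 0.12). Stab1 (-0.92 ± 0.12) and Fcgr2b (-0.69 ± 0.13) were among 6 of 27 phagocytic receptors that fell. Cell cycle genes fell in 4 of 39 (median -0.54, camera adjusted p = 9.44e-10, and adjusted p = 0.356 with an estimated correlation). The cell cycle list lay at a mean log2 CPM of 4.89, 6.08 and 5 in replicates 1 to 3, against 6.01 ± 0.25 in controls. Altogether 1375 genes rose and 662 fell, with 4256 at an unadjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 against 6), and 855 and 1453 under total-count scaling, which moved the median by -0.10. The count was 905 with the 2 groups fitted alone, 772 without young β-glucan 24 h replicate 1 and 1057 without replicate 3.

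Aged macrophages followed at 24 h of β-glucan. Some interferon-stimulated genes, MHC class I genes, antioxidant enzymes and osteoclast markers rose, and the Fc receptor gene Fcgr2b fell. The interferon signature differed widely between the 3 aged libraries, with levels of the interferon-stimulated genes at 4.72, 3.77 and 3.19 against 3.10 ± 0.29 in aged controls. Slc7a11 (2.97 ± 0.36, edgeR adjusted p = 2.9e-06) and Procr (2.96 ± 0.23, adjusted p = 6.89e-11) were among the 5 largest rises, beside H2-M2 (3.83 ± 0.4), Slamf8 (3.41 ± 0.46) and Src (2.98 ± 0.52). The calls of the last 3 ended with the groups fitted alone (edgeR adjusted p = 0.0827, 0.122 and 0.13). Fcrls (-1.38 ± 0.28) and Rnase4 (-1.29 ± 0.25) fell, and their calls also ended in that fit (0.219 and 0.215). Fcgr2b (-0.86 ± 0.14) fell as well. The arginine-recycling enzyme Ass1 (2.31 ± 0.21, edgeR adjusted p = 8.73e-09) rose (ENSMUSG00000076441, chromosome 2, 31470207 to 31520672), as did Acod1 (2.93 ± 0.32), Tnf (0.96 ± 0.21) and Il1rn (2.51 ± 0.3). Of 46 interferon-stimulated genes 19 rose and the other 27 did not pass (median 0.78, 34 adjusted over the list alone, camera adjusted p = 7.33e-20, and adjusted p = 0.254 with an estimated correlation). Among them Irf7 (1.49 ± 0.35) lost its call with the groups fitted alone (edgeR adjusted p = 0.181), without aged control replicate 2 (0.0612) and aged β-glucan 24 h replicate 1 (0.204), and Zbp1 (2.29 ± 0.48) with the groups fitted alone (adjusted p = 0.248) and without aged β-glucan 24 h replicate 1 (0.167). Osteoclast genes rose in 6 of 10 (median 1.09, camera adjusted p = 1e-07, estimated 0.00892). NRF2 genes rose in 14 of 25 (median 0.44, camera adjusted p = 3.43e-18, and adjusted p = 0.0559 with an estimated correlation), with Prdx6 (1.13 ± 0.11) and Fth1 (0.65 ± 0.11). MHC class I genes rose in 11 of 21 (camera adjusted p = 2.1e-11, and adjusted p = 0.143 with an estimated correlation). Lysosomal genes rose in 11 and fell in 2 of 36 (camera adjusted p = 1.41e-06, and adjusted p = 0.143 with an estimated correlation), with Ctsz (0.69 ± 0.095) and Gla (0.39 ± 0.074).

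In aged cells at 24 h 709 genes rose and 213 fell, and 3156 had an unadjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 against 3), or 482 and 416 under total-count scaling. The count was 312 without aged β-glucan 24 h replicate 1, the library with the highest interferon signature, 401 without aged control replicate 2, 535 without aged control replicate 1 and 214 with the groups fitted alone. No gene differed in its 24 h response between the ages (0 by edgeR, 516 with an unadjusted p below 0.05, 2 called by DESeq2). Interferon-stimulated genes had a median difference of -0.28 (camera adjusted p = 8.3e-05), but adjusted p = 0.88 with an estimated correlation, and Rsad2 (-1.04 ± 0.44, edgeR adjusted p = 1) did not pass.

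**Figure D2:**
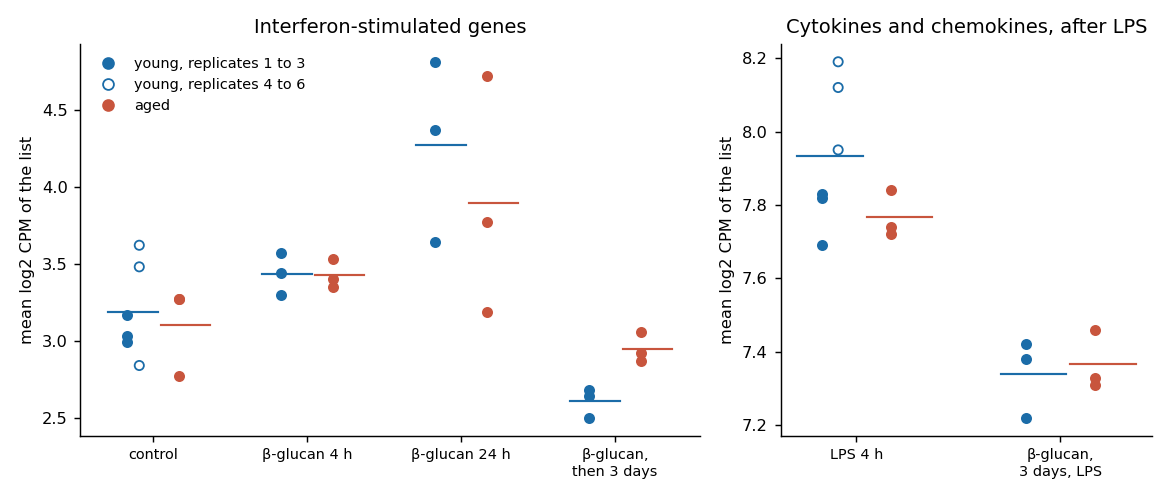
Mean log2 CPM of the interferon-stimulated genes without LPS (left) and of the cytokine and chemokine list after LPS (right), each point a library and each bar the group mean. Interferon-stimulated genes at 24 h ran from 3.64 to 4.81 in young and 3.19 to 4.72 in aged libraries. The cytokine list lay at 7.34 ± 0.11 in primed and 7.93 ± 0.19 in naive young cells (both sets, -0.44 within replicates 1 to 3).

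The third time point was 3 days after β-glucan. Few genes were called on day 3. The integrin gene Itgb3 and some lysosomal genes were higher, and the bacterial sensors Tlr2 and Fpr1 were lower. In young cells the immune-inhibitory ligand Cd200 (1.99 ± 0.24, edgeR adjusted p = 1.11e-05, ENSMUSG00000022661, chromosome 16, 45382135 to 45409053) and Itgb3 (1.48 ± 0.24, adjusted p = 0.000664, ENSMUSG00000020689, chromosome 11, 104608000 to 104670476) were highest, Itgb3 at 35.3 ± 0.24 against 11 ± 2.8 CPM. Dach1 (1.29 ± 0.19), Procr (1.27 ± 0.2) and Ccl4 (1.15 ± 0.12) were higher too. F13a1 (-2.24 ± 0.35, edgeR adjusted p = 0.000459), the formyl peptide receptor Fpr1 (-1.46 ± 0.2, adjusted p = 7.43e-05, ENSMUSG00000045551, chromosome 17, 17876471 to 17883940) and Siglece (-1.09 ± 0.17) were lower, and so were Tlr2 (-0.80 ± 0.12), Stab1 (-0.68 ± 0.12) and the macrophage marker Adgre1 (-0.44 ± 0.082). Of 36 lysosomal genes 4 rose and the other 32 did not pass (median 0.15, 15 up adjusted over the list alone), with Gpnmb (0.67 ± 0.098) and Gla (0.39 ± 0.069). The lysosome and osteoclast lists, the second with 1 of 10 up, passed (camera adjusted p = 4.97e-13 and 6.98e-05), also with an estimated correlation (both 0.047). Interferon-stimulated genes were below controls as a set (median -0.31, camera adjusted p = 2.81e-08, and adjusted p = 0.731 with an estimated correlation). In all 96 genes rose and 42 fell (1678 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 against 6), or 76 and 81 under total-count scaling. The count was 251 by DESeq2, 395 without the set term and 240 with a replicate block. It was 91 without young control replicate 1, 216 without control replicate 5, and 85, 70 and 78 without β-glucan 3-day replicates 1, 2 and 3.

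In aged cells on day 3 the same direction was seen for several of these genes. F13a1 and Fpr1 were lower and the engulfment factor Mfge8 was higher, and the activating receptor gene Pilrb1, which shares sequence with its neighbour Pilrb2, was lower. Pilrb1 (-1.13 ± 0.17, edgeR adjusted p = 0.000695, ENSMUSG00000066684, chromosome 5, 137852147 to 137858106) kept its call under all alternatives run. F13a1 (-2.04 ± 0.36, edgeR adjusted p = 0.00754) lost its call without aged control replicate 2 (adjusted p = 0.0638) and aged β-glucan 3-day replicate 1 (0.136), Fpr1 (-1.37 ± 0.23, adjusted p = 0.0049) without aged control replicate 2 (adjusted p = 0.0759) and aged β-glucan 3-day replicate 1 (0.127), and Mfge8 (0.89 ± 0.14, adjusted p = 0.00208) without aged control replicate 2 (adjusted p = 0.0638) and aged β-glucan 3-day replicate 1 (0.0517). The calls of Cd200 (1.37 ± 0.28), Itgb3 (1.17 ± 0.26) and Procr (1.11 ± 0.23) ended in 4, 9 and 6 of 14 alternatives (adjusted p up to 0.208, 0.291 and 0.306). Cd200 lost it without aged control replicates 2 (edgeR adjusted p = 0.208) and 3 (0.111) and aged β-glucan 3-day replicates 1 (0.179) and 3 (0.0834). Itgb3 lost it under RLE scaling (edgeR adjusted p = 0.0514), without the count filter (0.0735), without the set term (0.0754), with a replicate block (0.0697), without aged control replicates 1 (0.291), 2 (0.208) and 3 (0.0731) and aged β-glucan 3-day replicates 1 (0.231) and 3 (0.213). Procr lost it with the groups fitted alone (edgeR adjusted p = 0.081), without aged control replicates 1 (0.0502), 2 (0.208) and 3 (0.119) and aged β-glucan 3-day replicates 1 (0.306) and 3 (0.12). Lysosomal genes had a median of 0.13 and osteoclast genes of 0.54 (camera adjusted p = 2.01e-09 and 9.3e-05, each with adjusted p = 0.087 with an estimated correlation). Endothelial genes, 2 of 6 called adjusted over the list alone, had a median of 0.42 (camera adjusted p = 0.00325, estimated 0.0317). In all 24 genes rose and 15 fell (1365 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 against 3), or 18 and 23 under total-count scaling. The count was 106 by DESeq2, 95 with a replicate block and 16 without the set term. It was 13 and 3 without aged control replicates 1 and 2, and 3 and 10 without β-glucan 3-day replicates 1 and 3. No gene differed in its 3-day effect between the ages (0 by edgeR, 498 with an unadjusted p below 0.05, 3 called by DESeq2).

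**Figure D3:**
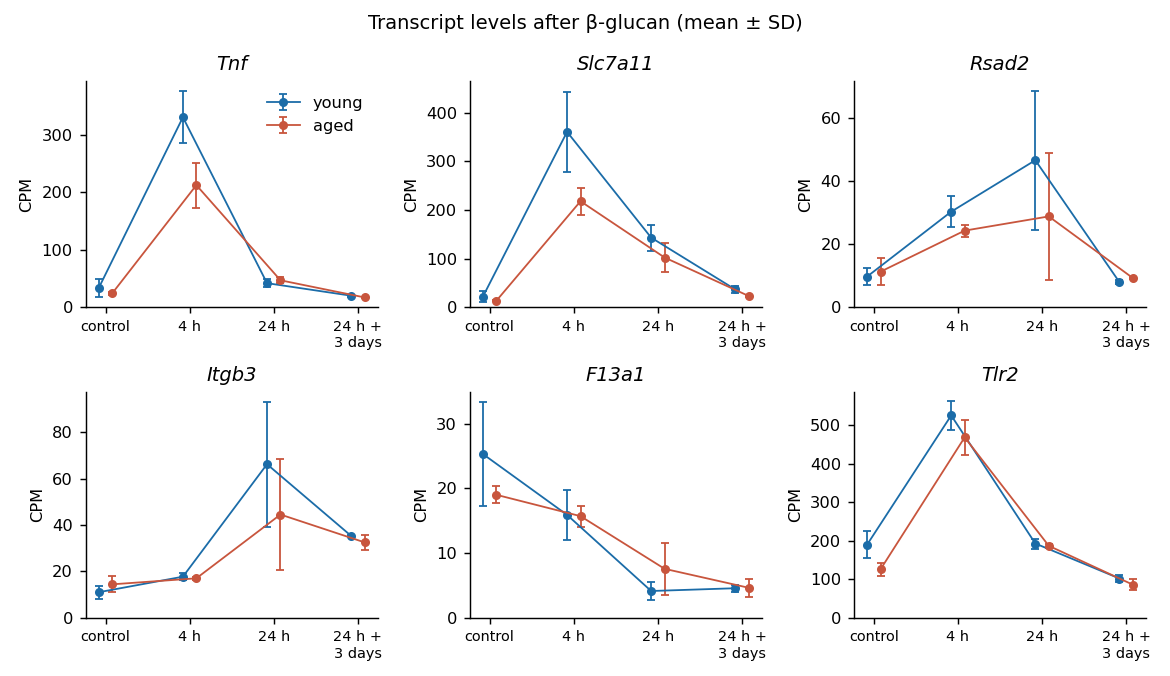
Levels of 6 genes in CPM (mean ± SD) in control cells and along the β-glucan time points, in young and aged cells, with 6 young control libraries and 3 libraries in each other group. Tnf and Tlr2 were highest at 4 h, Itgb3 and Rsad2 at 24 h, and F13a1 stayed below its control level on day 3 (4.56 ± 0.52 against 25.3 ± 8.1 CPM in young cells).

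LPS was given for 4 h to naive cells of each age. Cytokines, chemokines, interferon-stimulated genes and NF-κB components rose steeply, and the replication gene Mcm3 fell. In young cells Tnf rose from 33.3 ± 16 to 11000 ± 1800 CPM and in aged cells from 23.9 ± 2.4 to 8910 ± 590. Among genes with a mean log2 CPM of at least 3, the largest rises in young cells were in Cxcl10 (11.81 ± 0.44, edgeR adjusted p = 5.52e-21, ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), Ptgs2 (10.94 ± 0.33, ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), Rsad2 (10.88 ± 0.33), Oasl1 (10.84 ± 0.3) and Cmpk2 (10.51 ± 0.33). In aged cells Cxcl10 (12.45 ± 0.64), Oasl1 (12.36 ± 0.47), Ptgs2 (11.77 ± 0.49), Rsad2 (10.68 ± 0.46) and Cmpk2 (10.56 ± 0.47) led under this limit. Under it, the tetraspan gene Lhfpl2 (-5.86 ± 0.16, edgeR adjusted p = 2.5e-26, ENSMUSG00000045312, chromosome 13, 94057796 to 94195409), the cannabinoid receptor Cnr2 (-5.77 ± 0.22) and the transcription factor Lyl1 (-5.51 ± 0.16) fell most in young cells, beside Plekhg3 (-5.35 ± 0.15) and Snx24 (-5.34 ± 0.13). Lhfpl2 (-5.63 ± 0.22), Lyl1 (-5.58 ± 0.23), Cnr2 (-5.51 ± 0.3), Clspn (-5.36 ± 0.44) and Tmem86a (-5.31 ± 0.26) did in aged cells. For less abundant genes whose control libraries held 0 counts, the rise was at least 2110-fold (young) and 736-fold (aged) for Ifnb1, 42900-fold for aged Nos2 and 111000-fold for aged Il12b, from a floor of 3 counts over the group. Acod1 rose 412-fold and 852-fold, Ccl3 234-fold and 150-fold, and Ccl5 644-fold and 1110-fold in young and aged cells.

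All 34 cytokines rose with LPS in young cells (median 8.91, or 8.57 with 5 genes at 0 control counts set to their bound, camera adjusted p = 4.13e-19, estimated 0.00144) and all 34 in aged cells (median 8.85, or 8.57 with 5 such genes at their bound, adjusted p = 8.11e-22, estimated 0.000773). All 46 interferon-stimulated genes rose at both ages (median 6.28 and 5.98, both the same with the 1 gene at 0 control counts set to its bound), such as the cytosolic RNA sensor Ifih1 in young (6.56 ± 0.12) and aged cells (6.47 ± 0.17). The list passed in young cells (camera adjusted p = 1.14e-25, and adjusted p = 0.0604 with an estimated correlation) and in aged cells (adjusted p = 5.38e-30, estimated 0.0409). Of 28 NF-κB regulators 26 rose in young and 25 in aged cells, where 1 fell (camera adjusted p = 7.99e-14 and 4.91e-15, estimated 0.0403 and 0.029), with Irak3 (2.93 ± 0.081) and Nfkb1 (3.48 ± 0.07) in young cells. MHC class I genes rose in 19 of 21 at both ages (camera adjusted p = 1.57e-11 and 2e-12, with adjusted p = 0.0604 with an estimated correlation in young and 0.0409 in aged cells), with Tap1 (4.37 ± 0.11) and Nlrc5 (4.57 ± 0.11). Pattern receptors rose in 23 and fell in 6 of 34 at both ages (camera adjusted p = 1.23e-05 and 4.14e-06, with adjusted p = 0.0604 with an estimated correlation in young and 0.0409 in aged cells), with Myd88 (3.10 ± 0.072) and Aim2 (2.73 ± 0.072). Cell cycle genes fell in 33 of 39 in young and 28 in aged cells (median -1.57 and -1.44, camera adjusted p = 1.78e-06 and 2.5e-06, but adjusted p = 0.689 and 0.807 with an estimated correlation), such as Mcm3 in young (-2.50 ± 0.12) and aged cells (-2.05 ± 0.16). Altogether 5352 genes rose and 6126 fell in young cells (11895 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 6 against 6). In aged cells 4696 rose and 5102 fell (10509, n = 3 against 3). Total-count scaling moved the median of all genes by -0.80 and -0.73 and gave 2581 up and 10756 down in young and 2319 and 9532 in aged cells. No gene differed in its LPS effect between the ages (0 by edgeR, 1037 with an unadjusted p below 0.05, 7 called by DESeq2). With young replicates 4 to 6 alone 59 differed, and 1 did without young LPS replicate 3 or aged control replicate 2.

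Whether earlier β-glucan altered the state reached under LPS was read from primed against naive LPS cells, for which the labels state no 3-day interval. In young cells, primed macrophages held less of some cytokine, cholesterol synthesis and antioxidant transcripts, and more of Itgb3 and some lysosomal ones. Of these lists the cytokines alone passed with an estimated correlation. The same genes that marked day 3, Itgb3 and F13a1, differed here. Itgb3 (1.72 ± 0.27, edgeR adjusted p = 0.000141), Lhfpl2 (1.70 ± 0.19, adjusted p = 7.38e-07) and the activin subunit Inhba (1.56 ± 0.24, adjusted p = 8.78e-05, ENSMUSG00000041324, chromosome 13, 16011851 to 16031621) were higher, as were Snx24 (1.44 ± 0.18) and Ankrd13b (1.33 ± 0.22). F13a1 (-2.60 ± 0.39, edgeR adjusted p = 8.78e-05) was lowest, beside the leukotriene-cleaving enzyme Ggt5 (-1.10 ± 0.2), Ms4a6b (-1.04 ± 0.17) and Rpl41 (-1.16 ± 0.23), the last of which has many sequence copies. Of 34 cytokines 5 fell and the other 29 did not pass (median -0.37, 9 down adjusted over the list alone, camera adjusted p = 7.61e-07, estimated 0.00663). The granulocyte-macrophage factor Csf2 (-1.80 ± 0.38) fell, and so did Il12b (-0.73 ± 0.2, edgeR adjusted p = 0.032), whose call ended with DESeq2 (adjusted p = 0.466), without the count filter (0.074), with the groups fitted alone (0.201), without young LPS replicates 1 (0.0806) and 3 (0.101) and young β-glucan-then-LPS replicates 1 (0.0697), 2 (0.129) and 3 (0.112). The Toll-like receptor inhibitor Irak3 (-0.50 ± 0.1, edgeR adjusted p = 0.00195, ENSMUSG00000020227, chromosome 10, 120141648 to 120202130) fell. NF-κB regulators lay lower as a set (median -0.21, camera adjusted p = 0.00031, and adjusted p = 0.137 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 25 (median -0.30, camera adjusted p = 1.53e-09, and adjusted p = 0.0914 with an estimated correlation). NRF2 genes fell in 4 of 25 (median -0.26, camera adjusted p = 3.42e-07, and adjusted p = 0.137 with an estimated correlation), with the glutathione reductase Gsr (-0.63 ± 0.099). Of 36 lysosomal genes 5 rose and the other 31 did not pass (camera adjusted p = 0.000243, and adjusted p = 0.137 with an estimated correlation), with Gpnmb (0.56 ± 0.098) and Gla (0.38 ± 0.069). The lectin Clec4a2 (-0.96 ± 0.13), Tlr1 (-0.55 ± 0.12), Fcgr2b (-0.61 ± 0.13), Adgre1 (-0.40 ± 0.083) and Pf4 (-0.71 ± 0.15) fell. Interferon-stimulated genes had a median of -0.17 (camera adjusted p = 0.0056, and adjusted p = 0.487 with an estimated correlation).

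In young primed against naive LPS cells 431 genes were higher and 206 lower, and 2858 had an unadjusted p below 0.05 (edgeR quasi-likelihood test, n = 3 against 6). Total-count scaling gave 839 and 133, the fit without the set term 1385 in all, and the 2 groups alone 181 up and 223 down. The count was 421, 329 and 357 without β-glucan-then-LPS replicates 1, 2 and 3. Aged primed cells differed from aged naive LPS cells in fewer genes, again with some lower antioxidant genes and with lower cytokines as a set. The myeloid receptor Treml4 (-1.54 ± 0.24, edgeR adjusted p = 0.000404, ENSMUSG00000051682, chromosome 17, 48264295 to 48275360), Fpr1 (-0.97 ± 0.19, adjusted p = 0.00478), Clec4a2 (-0.76 ± 0.13, adjusted p = 0.00105) and Gsr (-0.60 ± 0.11, adjusted p = 0.0011) were lower under all alternatives run. Irak3 (-0.51 ± 0.11, edgeR adjusted p = 0.00799) was lower, without a call when aged LPS replicate 3 was left out (0.075). Lhfpl2 (1.30 ± 0.21, edgeR adjusted p = 0.000934) and Tnfrsf26 (1.04 ± 0.17, adjusted p = 0.000722) were higher, without calls when the groups were fitted alone (0.101 and 0.0509). Cxcl3 (-1.16 ± 0.21, edgeR adjusted p = 0.00304) was lower, and its call ended with DESeq2 (adjusted p = 0.254) and with the groups fitted alone (0.187). Of 34 cytokines 1 fell (median -0.28, 5 adjusted over the list alone, camera adjusted p = 1.56e-05, estimated 0.00688), and Il12b (-0.66 ± 0.2, edgeR adjusted p = 0.119) did not pass. NRF2 genes fell in 3 of 25 (median -0.33, 13 adjusted over the list alone, camera adjusted p = 2e-10, and adjusted p = 0.21 with an estimated correlation). In aged cells 107 genes were higher and 67 lower (2044 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 against 3), or 177 and 50 under total-count scaling and 41 and 76 with the groups fitted alone. DESeq2 called 329, the fit without the set term 99 and a single dispersion 113 (53 up and 60 down). Without aged LPS replicate 2 the count was 69, and without β-glucan-then-LPS replicates 2 and 3 it was 94 and 114. Between the ages 1 gene differed in this effect, the centrosomal Cep19 (-1.83 ± 0.327, edgeR adjusted p = 0.0281), named after its values were seen. A total of 923 had an unadjusted p below 0.05, and DESeq2 called 22. The count was 0 with a replicate block, with young replicates 1 to 3 alone, with a single dispersion and with the groups alone. It was 0 without young LPS replicates 1 or 3, young β-glucan-then-LPS replicates 2 or 3, aged LPS replicates 1 or 2, or aged β-glucan-then-LPS replicates 1 or 2. It was 2 without young β-glucan-then-LPS replicate 1, young LPS replicate 6 or aged LPS replicate 3, and 4 without aged β-glucan-then-LPS replicate 3.

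Primed cells were also compared over the genes that LPS itself moved most. The 198 genes most induced by LPS had a median of -0.25 in young primed cells (95% interval -0.31 to -0.19, 151 lower) and -0.22 in aged primed cells (-0.28 to -0.18, 156 lower). Camera gave p = 2.07e-06 and 6.22e-05, and 0.00223 and 0.00514 with an estimated correlation. The 200 most repressed genes had a median of 0.29 in young (0.1 to 0.5, p = 0.0136) and 0.03 in aged cells (0 to 0.31, p = 0.0327), with p = 0.15 and 0.155 with an estimated correlation. Under total-count scaling the repressed genes stood at 0.34 and 0.09 and did not pass, and without the count filter at 0.04 and 0, where the aged ones did not pass and their direction was reversed. In young cells they did not pass without young control replicate 5 (0.17) or young LPS replicates 4 (0.05) or 5 (0.34), and the median was 0.45 without LPS replicate 6 and 0.13 and 0.19 without β-glucan-then-LPS replicates 1 and 2. In aged cells they did not pass without young control replicates 5 (0.01) or 6 (0), young LPS replicates 4, 5 or 6 (0 each), aged LPS replicate 2 (0.09) or aged β-glucan-then-LPS replicates 2 (0.14) or 3 (0), and the median was 0.18 without aged LPS replicate 1, 0.07 without replicate 3 and 0.11 without aged β-glucan-then-LPS replicate 1. The direction was reversed without young LPS replicates 4, 5 or 6 and aged β-glucan-then-LPS replicate 3.

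How priming changed the LPS effect itself, counting the day-3 change before LPS, was tested as a difference of effects. In young cells some chemokines gained less from LPS, while some genes that LPS represses fell less. For a gene raised on day 3, such as Ccl4, the contrast also subtracts that rise. Ccl4 (-1.50 ± 0.16, edgeR adjusted p = 1.58e-07), Ccl3 (-0.89 ± 0.16) and Procr (-1.95 ± 0.26, adjusted p = 3.86e-05) gained less. Nuak1 (1.57 ± 0.23, edgeR adjusted p = 6.61e-05, ENSMUSG00000020032, chromosome 10, 84370905 to 84440597), Lhfpl2 (1.54 ± 0.23), Snx24 (1.42 ± 0.21) and Snx30 (1.29 ± 0.12, adjusted p = 2.21e-09, ENSMUSG00000028385, chromosome 4, 59805840 to 59904737) fell less, and Tlr2 (1.13 ± 0.15) gained more. Irak3 (-0.58 ± 0.13) gained less. The Ccl3 call ended with young replicates 1 to 3 alone (edgeR adjusted p = 0.0525), and that of Irak3 with young replicates 1 to 3 alone (adjusted p = 0.136), with the groups fitted alone (0.0879), without young β-glucan 3-day replicates 1 (0.0723) and 3 (0.0675) and young β-glucan-then-LPS replicates 2 (0.0766) and 3 (0.0928). The cytokine list had a median of -0.24 (3 of 34 called down, camera adjusted p = 0.0354, and adjusted p = 0.604 with an estimated correlation). In all 113 genes had a more positive and 66 a more negative effect (2137 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 or 6 per group), or 456 and 47 under total-count scaling, which moved the median by 0.13. DESeq2 called 372, young replicates 1 to 3 alone 49, the 4 groups alone 86, the fit without the set term 105 and without the count filter 111. Without single libraries the count was 68, 64 and 72 (β-glucan 3-day replicates 1 to 3), 93, 84 and 82 (β-glucan-then-LPS replicates 1 to 3), 109, 284 and 113 (control replicates 4 to 6), and 116 and 96 (LPS replicates 4 and 5). In aged cells 2 genes differed, Snx30 (0.79 ± 0.14, edgeR adjusted p = 0.0149) and Procr (-1.75 ± 0.3, adjusted p = 0.016), with 1254 at an unadjusted p below 0.05 and 34 called by DESeq2. The count was 1 without aged control replicates 2 or 3, 0 without β-glucan 3-day replicates 1 or 3, LPS replicate 2 or β-glucan-then-LPS replicate 2, and 4 without LPS replicate 3 or β-glucan-then-LPS replicate 1. The Snx30 call ended without the set term (edgeR adjusted p = 0.0746), with the groups fitted alone (0.108), without aged β-glucan 3-day replicates 1 (0.06) and 3 (0.0622), aged LPS replicate 2 (0.101) and aged β-glucan-then-LPS replicate 2 (0.12). The Procr call ended without the count filter (edgeR adjusted p = 0.0578), without aged control replicates 2 (0.0905) and 3 (0.116), aged β-glucan 3-day replicates 1 (0.197) and 3 (0.0838), aged LPS replicate 2 (0.101) and aged β-glucan-then-LPS replicates 2 (0.0881) and 3 (0.0525). Whether the young and aged differences differed from each other was not tested.

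Aged control cells were compared with young ones. Few genes differed, and among them were the bacterial sensors Fpr1 and Tlr2, lower in aged cells, and stromal genes had a higher median. Fpr1 (-1.16 ± 0.19, edgeR adjusted p = 0.00137) was lower under all alternatives run, and Sh3bgrl2 (-0.86 ± 0.14, adjusted p = 0.00137, ENSMUSG00000032261, chromosome 9, 83548327 to 83638801) lost its call in 1 alternative, without aged control replicate 3 (0.0514). The scavenger receptor Marco (-2.16 ± 0.47, edgeR adjusted p = 0.0258) was lower, and its call ended with young replicates 1 to 3 alone (adjusted p = 0.123), with the groups fitted alone (0.113), without young control replicates 3 (0.059) and 6 (0.0512) and aged control replicates 1 (0.193), 2 (0.076) and 3 (0.107). Ass1 (-1.26 ± 0.19, edgeR adjusted p = 0.000741) was lower, and its call ended with young replicates 1 to 3 alone (adjusted p = 0.0512) and with the groups fitted alone (0.0988). Tlr2 (-0.58 ± 0.11, edgeR adjusted p = 0.0068) was lower, at 126 ± 17 against 190 ± 35 CPM, and its call ended with young replicates 1 to 3 alone (adjusted p = 0.15) and without aged control replicates 1 (0.0667) and 3 (0.103). Adra1a (0.93 ± 0.16, edgeR adjusted p = 0.0033) and Plk2 (0.88 ± 0.13, adjusted p = 0.000723) were higher. The first call ended with young replicates 1 to 3 alone (edgeR adjusted p = 0.0644) and with the groups fitted alone (0.0793), and the second without the set term (adjusted p = 0.23) and with young replicates 1 to 3 alone (0.151). Of 13 stromal and fibroblast genes 1 was called and 12 were higher adjusted over the list alone (median 0.98, or 1.73 and 0.45 against young replicates 1 to 3 and 4 to 6, camera adjusted p = 7.6e-16, and adjusted p = 0.11 with an estimated correlation), with Sparc (0.97 ± 0.24, edgeR adjusted p = 0.0568) and Col1a2 (0.96 ± 0.28, adjusted p = 0.152). Mitochondrially encoded genes had a median of 0.28 (camera adjusted p = 6.71e-06, and adjusted p = 0.704 with an estimated correlation), which was -0.04 (-0.1 to 0.05) against young replicates 1 to 3 and 0.65 (0.6 to 0.69) against 4 to 6. In all 57 genes were higher and 21 lower (1643 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 against 6). The count was 65 against young replicates 1 to 3 and 958 against 4 to 6, with 11 higher, 6 lower and 1 in opposite directions against both. It was 159 by DESeq2, 31 without the set term, 152 with a single dispersion and 26 with the groups alone. It was 47, 145 and 42 without young control replicates 1, 2 and 3, and 30 and 17 without aged control replicates 1 and 3.

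The ages were compared under LPS as well. The insulin-degrading enzyme gene Ide and the aldo-keto reductase gene Akr1b8 were higher in aged cells, and Irak3, which damps Toll-like receptor signalling, was lower. Ide (0.85 ± 0.15, edgeR adjusted p = 0.0044, ENSMUSG00000056999, chromosome 19, 37268743 to 37337852), Akr1b8 (0.74 ± 0.13, adjusted p = 0.0042, ENSMUSG00000029762, chromosome 6, 34354119 to 34368463) and Sh3bgrl2 (-0.89 ± 0.13, adjusted p = 0.000839) were called under all alternatives run. Irak3 (-0.46 ± 0.093, edgeR adjusted p = 0.0108) was at 161 ± 16 against 222 ± 33 CPM, and its call ended with young replicates 1 to 3 alone (adjusted p = 0.262) and without aged LPS replicates 1 (0.12) and 2 (0.0588). Ust (-0.81 ± 0.15) and Adcy3 (-0.91 ± 0.18) were lower. The first call ended with young replicates 1 to 3 alone (edgeR adjusted p = 0.0794) and without aged LPS replicate 1 (0.0649), and the second with young replicates 1 to 3 alone (adjusted p = 0.28) and without aged LPS replicate 2 (0.109). Of 13 stromal genes 4 rose and 9 were higher adjusted over the list alone (median 1.10, or 1.54 and 0.57 against young replicates 1 to 3 and 4 to 6, camera adjusted p = 5.49e-10, and adjusted p = 0.112 with an estimated correlation). NF-κB regulators had a median of -0.22 (1 of 28 called lower, camera adjusted p = 3.62e-06, and adjusted p = 0.121 with an estimated correlation), which was -0.05 (-0.09 to -0.04) against young replicates 1 to 3 and -0.34 (-0.48 to -0.22) against 4 to 6. The cytokine list had a median of -0.18 (camera adjusted p = 0.0227, and adjusted p = 0.121 with an estimated correlation), which was -0.03 (-0.13 to 0.06) and -0.30 (-0.49 to -0.14) against these sets. In all 100 genes were higher and 58 lower (2109 with an unadjusted p below 0.05, edgeR quasi-likelihood test, n = 3 against 6), or 171 and 46 under total-count scaling. The count was 58 against young replicates 1 to 3 and 769 against 4 to 6, with 14 called against both. It was 274 by DESeq2 and 30 without the set term. Without young LPS replicates 1, 4 and 5 it was 80, 74 and 92, and without aged LPS replicates 1, 2 and 3 it was 20, 46 and 74.

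**Figure D4:**
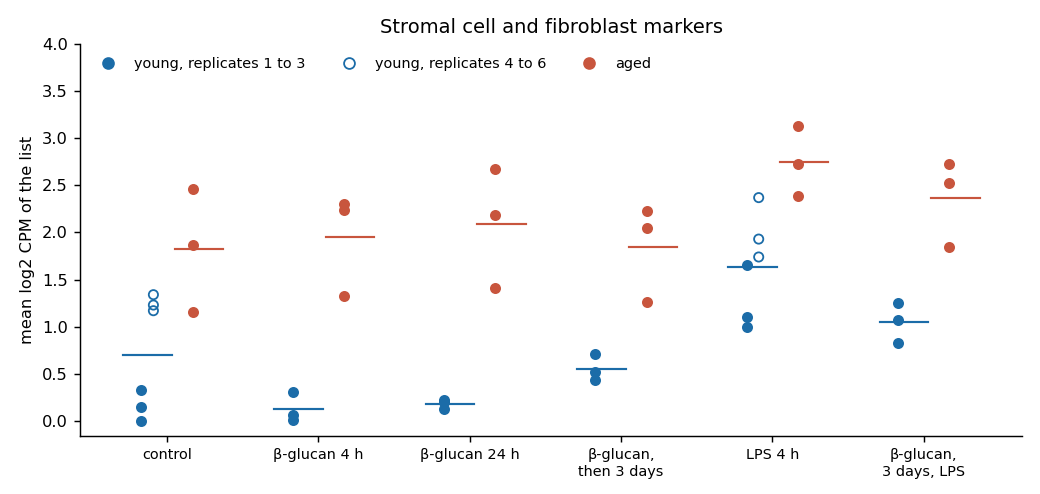
Mean log2 CPM of 13 stromal and fibroblast markers in each library, by treatment and age, with the bar at the group mean. The control groups lay at 0.70 ± 0.61 (young, with replicates 4 to 6 above 1 to 3) and 1.83 ± 0.65 (aged).

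To compare β-glucan and LPS effects in young cells, both were called against separate controls, β-glucan 4 h against replicates 1 to 3 and LPS against replicates 4 to 6. Of 13792 genes tested in both, 926 of 1333 genes higher with β-glucan were also higher with LPS, against 394.8 by independence. Of 1209 lower genes 885 were lower with both, against 433.2. Opposite directions were rarer, at 193 against 477.6 and 148 against 358.1. The correlation across genes was 0.422, and genes are not independent replicates. Any difference in culture time from the day-3 controls that both treatments shared was not separated. Without young β-glucan 4 h replicate 3 the genes lower with both numbered 564.

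Across genes, young and aged effects went the same way at each time. For genes called in at least 1 age the sign was shared in 2228 of 2295 at 4 h, 2173 of 2210 at 24 h, 141 of 146 on day 3, 11865 of 12106 under LPS, and 649 of 700 for priming under LPS. Called in both ages were 974, 749, 31, 9170 and 111 genes, of which 0, 0, 0, 2 and 0 had opposite signs. Over all tested genes the correlation was 0.272, 0.228, 0.0958, 0.849 and 0.0712, and over genes with a mean log2 CPM of at least 3 it was 0.885, 0.872, 0.651, 0.992 and 0.694. Genes are not independent replicates, so no p was attached.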

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

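The counts over other splits of the libraries, the tests of a non-responding share and of scaling for the cytokine pattern, the tests of the number of aged control libraries, and the intervals between libraries were chosen after the results were seen.

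Primed cells of both ages held less cytokine transcript under LPS than naive cells (list median -0.37 in young and -0.28 in aged cells). A share of cells that did not answer LPS was estimated from the 200 most repressed genes at 1.02% (95% interval 0.518 to 1.81), which lowers induced genes by at most -0.03, and the list stood at -0.42 (-0.52 to -0.24) in young replicates 1 to 3. With the spread between libraries the list mean differed by -0.44 (-0.66 to -0.22) in young and -0.40 (-0.57 to -0.23) in aged cells. Scaling was argued against too, since the highest median over TMM, RLE and total-count scaling in both ages was -0.23, and no interval between libraries reached 0 (nearest -0.65 to -0.11). Chance differences in handling would leave young and aged priming effects, which share no library, as unrelated as exchanged labels do, but they correlated at 0.156 over all tested genes, against at most 0.0902 in 99 exchanges (0.69 against 0.42 at a mean log2 CPM of at least 3). These are differences of mean log2 CPM in replicates 1 to 3, while the 0.0712 of the report is from fold changes of the model. Causes left open include a lasting effect of β-glucan, as a hypothesis, and a difference in culture time. The labels state the 3-day interval for primed, not for naive LPS cells.

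Stromal and fibroblast markers were higher in aged than in young cells (median 0.98 in controls and 1.10 under LPS, adjusted p = 0.11 and 0.112 with an estimated correlation, camera). Stromal cells carried over from whole marrow would raise all their abundant transcripts in 1 ratio, and Col1a2, Col1a1, Sparc, Acta2 and Bgn (24.4, 21.3, 15.3, 14.6 and 12.7 CPM on average) varied together over the 42 libraries, with a median correlation of 0.95. This does not part carry-over from shared regulation. Pdgfrb instead rose with LPS, from 1.02 to 15.2 CPM in young and 1.87 to 11.1 in aged cells. In aged controls the list lay higher by 1.73 (1.53 to 2) against young replicates 1 to 3 and by 0.45 (0.38 to 0.85) against 4 to 6. These intervals over markers had been set as the bound, but the markers vary together, so they leave out the spread between libraries. With it, the list mean differed by 1.67 (0.17 to 3.17) and 0.58 (-1 to 2.16) in controls and by 1.5 (0.68 to 2.32) and 0.73 (-0.06 to 1.53) under LPS. For the list as a whole, age and the difference between the young sets therefore cannot be told apart as causes. Igfbp5, chosen after its values were seen, stood at 0.0463 and 0.0533 CPM in the 2 young sets and at 0.772 in aged controls. A small share of stromal cells that differed between cultures is a candidate explanation. An age effect on these genes within macrophages was not tested, and 13 of the 15 listed markers were measured, none of them in another list.

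Fewer genes were called with β-glucan in aged than in young cells at each of the 3 times (1141 against 2128, 922 against 2037 and 39 against 138). The smaller number of aged control libraries was argued against as the whole cause, since young replicates 1 to 3 alone gave 2111, 2227 and 172 calls, 1.85, 2.42 and 4.41 times the aged counts. With the groups fitted alone, 3 against 3, the counts were 2563, 891 and 436 against 1292, 214 and 44, although 6 young controls gave 1802 at 4 h. The within-group variance in aged libraries was 1.1 times that in young ones at the median (1.17, 1.3, 0.811 and 1.89 in controls and at the 3 times). Among genes chosen by the mean effect of both ages, aged effects were 0.934, 0.872 and 0.913 times the young ones (95% intervals 0.911 to 0.967, 0.822 to 0.924 and 0.87 to 1.08). Larger spread and smaller effects cannot be told apart as causes, because both values fell between the bounds set for them, and the tests of the age differences themselves called 1, 0 and 0 genes (edgeR, 586, 516 and 498 with an unadjusted p below 0.05, and 6, 2 and 3 by DESeq2).

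Calls were counted again for other splits of the same libraries, refitted without the other groups and with the term for young replicates 4 to 6 wherever it could be separated from the split, so the counts for the real split differ from those of the report. In young cells chance was excluded for LPS (10415 genes against 0 at most in another split, 1 of 100 drawn giving as many). It was not decided for β-glucan at 4 h (1801 against 1768, 1 of 74) or 24 h (894 against 354, 1 of 74). Nor was it on day 3 (106 against 2861, 3 of 74) or for primed against naive LPS cells (378 against 1954, 2 of 74). The same held for the priming difference of the LPS effect (85 against 21, 1 of 50 drawn). In these, replicates 4 to 6 lay on 1 side of the real split and differed as a set, so the shares decide nothing. The split that parted replicates 4 to 6 from all others, without the term, gave the 1768, 2861 and 1954 genes, which points to sample structure. With young replicates 1 to 3 alone day 3 and priming called 172 and 463 genes. In aged cells the 10 splits of 3 against 3 are too few for a share under 0.05, with 1288 against 0 at 4 h (1 of 10), 196 against 0 at 24 h (1 of 10), 43 against 283 on day 3 (2 of 10), 8880 against 0 for LPS (1 of 10) and 116 against 0 for primed cells (1 of 10). The day-3 split with 283 genes also points to a structure of the samples. Chance was not excluded for age in controls (14 of 84 splits, 17 genes against 1572) or under LPS (5 of 84, 215 against 1282), where the high counts again point to a structure of the samples, nor for the aged priming difference (5 of 50, 2 against 32). For the 5 age differences the real split called 0 genes, so 50 of 50 drawn splits gave as many (highest other 1, 1069, 4, 2 and 0, the second again a sign of structure).

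Single libraries stood apart from the other 5 of their group in 10 of 146 values tested, where chance gives about 1 in 20. In young controls these were replicate 5 in the stress list (mean log2 CPM 6.20), Cd80 (log2 CPM 3.38) and Mrc1 (9.01) and replicate 2 in Ccl5 (1.32). In young LPS cells they were replicate 2 in pattern receptors (6.99) and antimicrobial effectors (7.29), replicate 5 in the citric acid cycle (6.15), replicate 3 in cholesterol synthesis (5.35), replicate 4 in the hypoxia list (3.96) and replicate 6 in Cd80 (5.45).

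Effects differed between groups, by tests of the difference, in 1 gene for age at 4 h of β-glucan (Ccl4, -1.02) and in 1 gene for age under priming (Cep19, -1.83). The LPS effect differed with priming in 179 genes in young and in 2 genes in aged cells (Snx30, 0.79, and Procr, -1.75).

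Gene lists also differed between the ages, but none passed both forms of the camera test (adjusted p from 0.0933 to 0.969 with an estimated correlation). At 4 h the medians were -0.26 for cytokines, -0.08 for oxidative phosphorylation, -0.16 for hypoxia, -0.11 for the stress list, -0.11 for ribosomal proteins and -0.16 for immediate early and heat shock genes. At 24 h they were -0.28 for interferon-stimulated genes, 0.11 for cholesterol synthesis, 0.24 for cell cycle and -0.10 for lysosome. On day 3 they were 0.22 for interferon-stimulated genes, -0.08 for oxidative phosphorylation and -0.07 for ribosomal proteins. For LPS they were 0.14 for NRF2 genes, -0.27 for mitochondrially encoded genes, -0.08 for ribosomal proteins and -0.25 for immediate early and heat shock genes.

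The LPS effect of primed minus naive young cells differed in 8 lists, with adjusted p from 0.604 to 0.69 with an estimated correlation (camera). Medians were -0.24 for cytokines, -0.24 for cholesterol synthesis, -0.27 for immediate early and heat shock genes and 0.35 for cell cycle. They were -0.09 for MHC class I, -0.02 for NF-κB regulators, -0.11 for NRF2 genes and -0.11 for ribosomal proteins, and these 4 turned to 0.04, 0.10, 0.02 and 0.02 under total-count scaling. In aged cells 4 lists differed (adjusted p from 0.835 to 0.852 with an estimated correlation, camera), with medians of -0.13 for glycolysis, -0.20 for NRF2 genes, 0.26 for mitochondrially encoded genes and -0.22 for cholesterol synthesis.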

How the results depend on the processing

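Alternatives added after seeing the data are named above. RLE scaling left each of the 19 counts of called genes within 1.5 times its value. For the values below the cause was not tested, except that leaving out libraries or groups leaves fewer samples and that the filter changes the number of tested genes. Of 3881 values of called genes named in the report, over all alternatives and libraries left out, 114 lost the call and the others kept it, and no value reversed. The depth of 39850835 counts or more per library left 17648 genes to test. Simulated data recovered 46.3% of genes changed 1.5-fold in the age difference on day 3, among genes with a mean log2 CPM of at least 3.

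With DESeq2 the counts were 251 and 106 for β-glucan on day 3 (young and aged), 329 for aged primed against naive LPS cells, 159 and 274 for age in controls and under LPS, 6, 2, 3, 7 and 22 for the age differences (4 h, 24 h, day 3, LPS, priming), and 372 and 34 for the priming difference of the LPS effect. Without the set term they were 395 and 16 on day 3, 1385 and 99 for primed cells, 31 and 30 for age in controls and under LPS, 0 for the age difference at 4 h, and 105 and 1 for the priming difference. With the groups fitted alone they were 905 and 214 at 24 h, 404 for young primed cells, 26 for age in controls, 86 for the young priming difference, and 0 for the age differences at 4 h and under priming. Without the count filter they were 111 and 1 for the priming difference and 0 for the age difference at 4 h. With young replicates 1 to 3 alone they were 58 for age under LPS, 49 for the young priming difference, and 0 for the age differences at 4 h and under priming, and with replicates 4 to 6 alone 958 and 769 for age in controls and under LPS and 59 for the age difference of LPS. Total-count scaling gave 972 for young primed cells and 503 for the young priming difference, and a single dispersion 113 for aged primed cells, 152 for age in controls and 0 for the age difference under priming. Beside these counts of 0, edgeR gave 586 and 923 genes with an unadjusted p below 0.05 for the age differences at 4 h and under priming in the reported fit, and DESeq2 called 6 and 22.

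Replicate numbers may pair the samples. The median correlation of same-numbered libraries was 0.01 in young and 0.04 in aged cells, and of others -0.01 and -0.02. Of 45 pairs 0 and 1 were over 0.1, but 16 and 17 of 18 libraries correlated best with their own number. With the replicate number as a block the count was 240 and 95 on day 3 (young and aged) and 0 for the age difference under priming, and no other count run with it moved by over 1.5 times. Age in controls and under LPS was not run with the block.

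The LPS-repressed genes had a median of 0.34 in young and 0.09 in aged primed cells under total-count scaling, without passing, and of 0 in aged cells without the count filter. Over genes with a mean log2 CPM of at least 3 the young to aged correlation was 0.885, 0.872, 0.651, 0.992 and 0.694 (4 h, 24 h, day 3, LPS, priming).

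Leaving out single libraries, the counts ran from 1434 to 2404, 772 to 2995, 70 to 216, 11239 to 11358 and 329 to 682 in young cells (4 h, 24 h, day 3, LPS, primed cells), and from 755 to 955, 312 to 1062, 3 to 58, 9151 to 9220 and 69 to 125 in aged cells. They ran from 17 to 145 and 20 to 178 for age in controls and under LPS, from 0 to 1, 0 to 0, 0 to 0, 0 to 1 and 0 to 4 for the age differences, and from 64 to 284 and 0 to 4 for the priming difference in young and aged cells. The median of the LPS-induced genes ran from -0.30 to -0.23 in young and -0.32 to -0.16 in aged primed cells, and that of the repressed genes from 0.05 to 0.45 and 0 to 0.18. Genes higher with both β-glucan and LPS numbered 661 to 995 and lower ones 564 to 948, and the young to aged correlation ran from 0.232 to 0.286, 0.159 to 0.235, 0.061 to 0.102, 0.824 to 0.849 and 0.0505 to 0.0811. Where leaving out a library left 2 in a group, the spread was pooled over all groups.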

Other observations

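Antimicrobial effector genes followed LPS at both ages. Of 25 measured 19 rose in young cells (median 1.70, camera adjusted p = 3.79e-07, and adjusted p = 0.0781 with an estimated correlation) and 18 in aged cells (median 1.52, the same with 2 genes at 0 control counts set to their bound, camera adjusted p = 9.06e-08, and adjusted p = 0.0699 with an estimated correlation). Among them were the inflammatory caspases Casp4 (4.08 ± 0.084 and 3.85 ± 0.12) and Casp1 (2.81 ± 0.088 and 2.65 ± 0.12) and the immunity-related GTPase Irgm1 (5.16 ± 0.14 and 5.12 ± 0.2). β-Glucan raised 7 of the 25 in aged cells at 4 h (median 0.42, camera adjusted p = 6.75e-09, and adjusted p = 0.0697 with an estimated correlation), with Casp4 (1.13 ± 0.11) and Acod1 (4.42 ± 0.34). At 24 h 9 rose (median 0.56, camera adjusted p = 7.85e-11, and adjusted p = 0.128 with an estimated correlation), with Cyba (0.74 ± 0.11), a subunit of the NADPH oxidase. Immediate early and heat shock genes rose in 8 of 17 in young cells at 4 h (median 0.45, camera adjusted p = 0.000522, and adjusted p = 0.144 with an estimated correlation), such as Junb (0.94 ± 0.19) and Jun (0.59 ± 0.12), whose calls ended without the set term (edgeR adjusted p = 0.109 and 0.362).

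Young replicates 4 to 6 differed from 1 to 3 in 3074 genes over both treatments (edgeR quasi-likelihood test). Among controls 1557 differed (915 higher, 642 lower) and under LPS 901 (570 higher, 331 lower). Among the largest differences over both treatments, named after their values were seen, were Col1a1 (1.48), Fscn1 (1.28) and Col1a2 (1.27) higher in replicates 4 to 6, and Rn7sk (-3.64), Lars2 (-1.44) and Atp6v0d2 (-1.22) lower. Mitochondrially encoded genes took 1.81 ± 0.11% of counts in young control replicates 1 to 3 and 1.16 ± 0.046% in 4 to 6. The labels give no batch or date.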
